A study of Mus musculus with 16 samples.

How the data were processed

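Libraries were prepared from spinal cord RNA with a stranded mRNA kit, per the labels' protocols. The authors deposited a single table of genes by libraries, in which some values are not whole numbers and column totals differ. These features alone do not tell estimated counts from counts that were already normalized. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here. The submitters' processing notes name DESeq2 and R without saying what each was used for.

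Each sample was placed in its group by its title. The names of the 16 value columns were compared with the sample titles after case and punctuation were removed, and 0 matched, so 16 columns of values were not used. The tests chosen in advance, on differential expression, gene lists and list scores, were not run. Gene identifiers were paired with symbols through a table of gene names, which left 346 identifiers without a symbol, and gene types were taken from GENCODE M21, where 55227 of the identifiers were found. No coordinates are given because the build of the table is not stated.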

Results

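The series covered naive mice and mice with experimental autoimmune encephalomyelitis (EAE), an induced inflammatory disease of the mouse central nervous system, the latter with and without inhibition of BTK, a kinase of B cell receptor and Fc receptor signalling. Polyadenylated RNA of spinal cord was sequenced in bulk from 16 samples in 3 groups. The labels gave 6 samples from EAE mice that received vehicle, 6 from EAE mice that received the inhibitor and 4 from naive mice that received vehicle. The design implied 3 comparisons, which were EAE against naive, inhibitor against vehicle within EAE, and inhibitor-treated EAE against naive.

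None of these comparisons is reported. The deposited expression table had 16 value columns named by library codes, and 0 of the 16 codes occurred in the title of any sample. All 16 columns were therefore left unused, and no expression level, fold change or depth per sample is given. The equal number of columns and samples does not say which column belongs to which sample, and assignment by position or by expression level was not attempted.

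The table listed 55487 distinct mouse Ensembl gene identifiers, of which 55141 (99.38%) were paired with a gene symbol. Among the identifiers found in the GENCODE M21 annotation, 21974 belonged to protein-coding genes, 9937 to processed pseudogenes and 5614 to lincRNA genes. Gene lists for cell types and pathways, and a list of sex-linked check genes, had been fixed before the data were examined. Of 711 list memberships in 45 lists, 707 were matched by symbol to an identifier in the table. Every member was matched in 42 of the 45 lists. Examples were the lists for homeostatic microglia (14 genes), B cells (16), T cells (25), mature oligodendrocytes and myelin (18), and BTK and Fc receptor signalling (21). The unmatched symbols were Rigi, Ahsp, Atp5f1a and Atp5f1b. Matching was by symbol only, so an unmatched symbol does not show that its gene had no row. Rigi, Atp5f1a and Atp5f1b are newer symbols of Ddx58, Atp5a1 and Atp5b, which stood in the same lists and were matched. Those genes therefore had rows, and the memberships count each of them under both symbols. Whether Ahsp had a row under another symbol was not examined. A listed identifier says only that the gene had a row in the table, not that it was expressed.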

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

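Searches added after seeing the data, through every label and the design text and with only the first part of each column name, also matched 0 of the 16 columns. Looking up gene identifiers in GENCODE M21 instead of the table of gene names found 55227 rather than 55141. The alternatives planned for normalization, filtering, tool, threshold and left-out libraries were not run, because no column of values was used. No paired analysis was possible because the columns carry no replicate number or group from the labels. The sample titles also do not say that the same replicate number in different groups marks related samples. The design is therefore not known to be paired, and a key from columns to samples would not by itself allow pairing.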
